A study of Arabidopsis thaliana with 4 samples.

How the data were processed

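Messenger RNA of 2-week-old Arabidopsis thaliana seedlings was measured by RNA sequencing in Col-0 wild type plants and in a mutant of the long intergenic noncoding RNA lincRNA11195, each untreated or after 12 h of abscisic acid (ABA). Each of the 4 groups held 3 biological replicates per the series text, which gave 12 libraries. Per the labels, seedlings grew on MS-based medium, total RNA was extracted with Trizol and treated with DNase, and libraries were made with a stranded mRNA kit. The processing notes of the authors name Trim Galore 0.3.3, edgeR without a version, and the TAIR10 build. The aligner, the counting tool, and whether counting used the strand are not given in the sources used here.

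The deposited table holds raw counts, whole numbers per gene for each of the 12 libraries, with no normalization by the authors that the values show. It lists 33610 gene IDs, of which 32843 matched the TAIR10.1 annotation used for names, gene order, exonic length and GC content, and 767 did not. Among the IDs, 279 belonged to the organelle genomes and 3911 carried a transcript suffix, of which 3909 were pseudogenes in the annotation. No positions are given, because the labels name TAIR10 and the annotation is TAIR10.1. Total counts ranged from 14691544 in mutant untreated replicate 1 to 22477294 in mutant untreated replicate 3.

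Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, which left 21322 genes holding 99.96% of all counts, libraries were scaled with TMM factors, and 1 quasi-likelihood model was fitted with a mean per group. The common biological coefficient of variation was 0.185. A gene was called when its Benjamini-Hochberg adjusted p in that comparison was under 0.05. The 5 comparisons were ABA against untreated in wild type, ABA against untreated in the mutant, mutant against wild type untreated, mutant against wild type under ABA, and the interaction, which is the ABA response in the mutant minus that in wild type. Every printed adjusted p for a gene comes from this model unless another setting is named. The standard error of a log2 fold change was its absolute value divided by the square root of its F statistic. Levels are TMM-normalised CPM from edgeR, as means ± SD over 3 libraries. Where a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group, and where it had 1 to 3 counts, the ratio is given with its counting interval. Such bounds and intervals cover counting error only.

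Before the data were examined, 20 gene lists with 314 genes were fixed from general knowledge: ABA-induced markers, clade A PP2C phosphatases, PYR/PYL ABA receptors, SnRK2 kinases, ABA transcription factors, ABA synthesis and breakdown, light harvesting and Rubisco small subunit, expansins, mitotic cell cycle, auxin early response, jasmonate synthesis and response, salicylate and defence, CBF, DREB2 and ZAT factors, heat shock, glucosinolate synthesis, flavonoid and anthocyanin synthesis, circadian clock, leaf senescence, root tissue markers, and seed and embryo markers. A list member counted as measured when it passed the filter. Lists were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with the fry rotation test, each adjusted over the 20 lists of a comparison. The interaction was also tested with fry over the 6429 genes raised and the 6877 lowered by ABA, adjusted over both sets. Named genes followed a rule set at the same time. In each comparison it took the 10 called genes with the largest rise and the 10 with the largest fall among nuclear genes that reached at least 5 CPM in the higher group and whose replicates did not overlap. It added up to 4 members of each list with the smallest adjusted p, and a panel of RD29A, RD29B, RAB18, ABI1, HAI1, NCED3, CYP707A3 and PYL4. For the interaction, the replicate differences between ABA and untreated libraries had not to overlap between genotypes. Any other gene named was chosen after its values were seen, and the text says so.

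The workflow was tested on simulated data with a spread like that of these libraries. Of genes simulated with a 4-fold rise, 96% were called in the comparison of untreated genotypes and 86% in the interaction, and of those with a 2-fold rise, 58% and 28%. False calls made up 3.03% to 6.82% of the calls. Each simulation changed 50 genes for each fold, fewer than were called in the data, and drew genes independently without a GC trend. These shares may therefore differ from those in the real data. Replicate numbers were checked for pairing. Of 18 pairs of libraries with the same number in different groups, 6 had correlated residuals above 0.1. The range was -0.363 to 0.537 and the median -0.0095, against a median of 0.002 for different numbers. Libraries were therefore treated as unpaired. Between wild type ABA and mutant ABA, however, same-numbered libraries had 0.537, 0.06 and 0.35, so a pairing within the ABA groups is not excluded. Pairs with different numbers reached up to 0.567.

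The alternatives set in advance were size factors by relative log expression, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of at least 1 CPM in 3 libraries, exclusion of organelle genes, the replicate number as a block, a fit of only the groups compared, a minimum absolute log2 fold change of 1, and each of the 12 libraries left out in turn. After the data had been seen, 2 more were added. The first left out wild type untreated replicate 1 and mutant untreated replicate 1 together. The other corrected each library for exonic length and GC content with lowess curves of log2 CPM. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.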

Results

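The data comprised 12 RNA sequencing libraries from 2-week-old seedlings, with 3 biological replicates in each of 4 groups: wild type untreated, wild type with ABA, mutant untreated and mutant with ABA. ABA is the plant hormone that accumulates in drought and closes stomata. Wild type untreated libraries held 18250616 to 19338277 counts, wild type ABA libraries 20695204 to 21861665, mutant untreated libraries 14691544 to 22477294 and mutant ABA libraries 17988131 to 19262909. A floor of 3 counts in a library corresponded to 0.134 to 0.204 CPM before TMM scaling. The treatment separated the libraries along the first principal component, with 67.4% of the variance, and the second, with 16.3%, separated the genotypes, with all wild type libraries above all mutant libraries. The 100 genes with the most counts took 17.3% to 18.0% of counts in untreated wild type libraries, 12.8 ± 1.56% in the untreated mutant (mean ± SD, n = 3), 11.3 ± 0.558% in wild type with ABA and 10.2 ± 0.742% in the mutant with ABA.

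**Figure D1:**
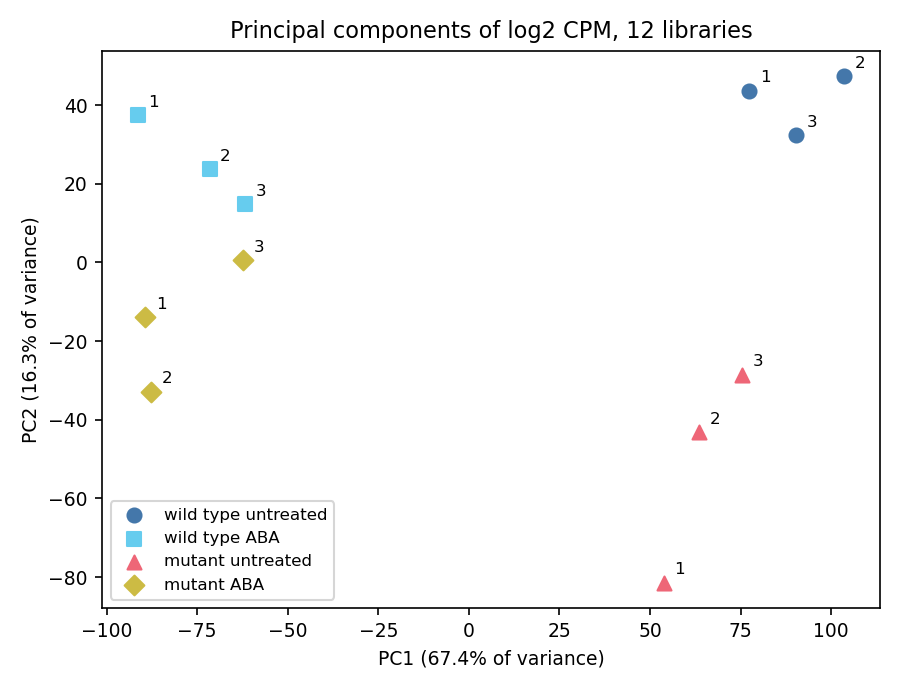
Principal components of log2 CPM, with PC1 (67.4% of variance) on the horizontal axis and PC2 (16.3%) on the vertical axis. Each point is 1 of the 12 libraries, numbered by replicate and marked by group. The ABA libraries lie at negative PC1 and the untreated ones at positive PC1, and mutant untreated replicate 1 has the lowest PC2.

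The transcript that defines the mutant, lincRNA11195, was not analysed here, since the annotation names no gene by it. All statements on the mutant rest on the group labels. The labels name a single mutant, so other differences between its seed line and wild type cannot be told apart from the mutation.

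After 12 h of ABA, wild type seedlings held many times more of the transcripts that the hormone is known to induce. RD29A, a gene induced by drought and cold, rose by 4.54 ± 0.33 on the log2 scale (± SE, n = 3 per group), RD29B by 6.23 ± 1.24, and RAB18, which encodes a dehydrin, by 4.70 ± 0.73. Of the 33 measured ABA-induced markers, 31 rose and none fell, and 31 rose when adjusted over the list alone (median log2 fold change 4.02; camera adjusted p = 4.97e-17, and adjusted p = 0.0878 with an estimated correlation). All 8 measured clade A PP2C phosphatases, which are negative regulators of ABA signalling, rose as well. They included ABI1 at 3.06 ± 0.21, which went from 60.1 ± 6.92 to 499.7 ± 109 CPM, and HAI2 at 6.90 ± 0.42 (camera adjusted p = 3.36e-07, and adjusted p = 0.0966 with an estimated correlation). Among the largest rises was RD20, a caleosin gene, at 7.84 ± 0.49. The small heat shock gene HSP22 reached 167.9 ± 19.6 CPM with ABA, and its untreated counts all lay in replicate 1 (1.87 CPM). That library held more of several ABA-induced transcripts than the other 2, and without it the rises were 11 for RD29B, 6.17 for RAB18 and 7.97 for HAI2. After a correction for gene length and GC content, RD29B and RAB18 rose by 6.98 and 5.72. AT2G35070 and AT5G04380 had 0 counts in untreated wild type and were at least 179-fold and at least 101-fold higher with ABA.

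The receptors of the hormone went the other way. Of the 10 measured PYR/PYL ABA receptors, 7 fell, while PYL3 at 2.21 ± 0.62 and PYL7 at 0.88 ± 0.15, which were chosen after their values were seen, rose (camera adjusted p = 0.00174, and adjusted p = 0.174 with an estimated correlation). PYL4 fell from 79.8 ± 15.5 to 1.96 ± 0.557 CPM (log2 fold change -5.35 ± 0.24), and PYL6 from 1135 counts to 3, a ratio of 487 with a counting interval of 166 to 2370. Of the 10 SnRK2 kinases, which act downstream of the receptors, 8 rose, led by SNRK2.7 at 2.74 ± 0.21, and SNRK2.5, chosen after its value was seen, fell (-0.54 ± 0.20). Of the 9 ABA transcription factors, 8 rose (9 adjusted over the list alone), among them ABF3 at 2.83 ± 0.18 and MYB96 at 3.09 ± 0.23. Of 11 genes of ABA synthesis and breakdown, 10 rose. They included NCED3, whose enzyme makes the precursor of ABA (3.16 ± 0.36, and 3.83 after the length and GC correction), and CYP707A1, whose enzyme inactivates ABA (4.72 ± 0.16), while ABA2, chosen after its value was seen, fell (-0.71 ± 0.19). Camera adjusted p was 0.00185, 1.94e-05 and 5.95e-06 for these 3 lists, and adjusted p was 0.174, 0.0878 and 0.0712 with an estimated correlation.

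Most of the measured light harvesting, expansin and mitotic cell cycle genes fell. Of the 24 measured light harvesting and Rubisco small subunit genes, 22 fell (23 adjusted over the list alone), with a median of -2.13 (camera adjusted p = 6.73e-08, and adjusted p = 0.274 with an estimated correlation). LHCB6 and LHCB4.1, antenna proteins of photosystem II, changed by -3.47 ± 0.30 and -2.91 ± 0.28. After the length and GC correction 15 of the 24 were called, the median was -1.49, LHCB6 and LHCB4.1 were at -1.93 and -1.71, and the call of LHCB1.5 was lost. Of 17 expansins, which loosen cell walls, 15 fell and EXPA16 rose by 2.62 ± 0.19, or 3.27 after the length and GC correction (camera adjusted p = 5.95e-06, and adjusted p = 0.266 with an estimated correlation). EXPA8 went from 616 counts to 2, a ratio of 397 with a counting interval of 109 to 3280. Of 15 mitotic cell cycle genes, 10 fell, such as CDC20.1 at -1.27 ± 0.19, and of 17 root tissue markers, 9 fell and CASP5 rose by 3.69 ± 0.52. Camera adjusted p was 0.00238 for the cell cycle and 0.0398 for the root markers, and adjusted p was 0.429 and 0.466 with an estimated correlation.

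Of 16 heat shock genes, 12 rose, and of 12 flavonoid and anthocyanin synthesis genes, 8 rose, among them the regulator PAP2 at 3.77 ± 0.31, and CHS, which encodes chalcone synthase and was chosen after its value was seen, fell (-1.28 ± 0.32). Of 11 leaf senescence genes, 10 rose (11 adjusted over the list alone), led by the sugar transporter gene SWEET15 at 7.10 ± 0.64 (9.14 without wild type untreated replicate 1). Camera adjusted p was 6.11e-06, 0.00125 and 2.09e-05 for these 3 lists, and adjusted p was 0.0803, 0.274 and 0.266 with an estimated correlation. Of 14 circadian clock genes, 5 rose and 1 fell, with CCA1 at 3.43 ± 0.26 and GRP7 at -1.88 ± 0.35, or -0.95 after the length and GC correction. Counts of genes that rose and fell were 7 and 2 of 20 for jasmonate synthesis and response, 3 and 4 of 19 for salicylate and defence, 3 and 6 of 15 for auxin early response, 1 and 7 of 19 for glucosinolate synthesis, and 3 and 0 of 7 for CBF, DREB2 and ZAT factors. Camera passed for none of these 5 lists or the clock (lowest adjusted p = 0.0856), while the fry test passed for auxin, lower, and for the CBF, DREB2 and ZAT factors and the clock, higher (adjusted p = 0.00383, 0.00628 and 0.00894). Fry also passed for all 13 lists that camera passed in this comparison. The labels state no harvest time. A difference in it between ABA and untreated libraries, of either genotype, could also change clock genes and was not tested. Of the seed and embryo markers only OLEO4 was measured, and it fell from 45 counts to 2, a ratio of 29 with a counting interval of 7.57 to 247. In all, 5376 genes were higher and 6012 lower with ABA in wild type, 53.4% of those tested. Reads of rRNA, snoRNA and snRNA genes went from 0.1365% to 0.0852% of counts, and organelle genes from 0.1083% to 0.0499%. Fold changes fell with GC content (Spearman rho -0.242 across genes), to a median of -0.65 in the 10% of genes with the highest GC. After the length and GC correction 5999 were higher and 6053 lower, including 87.5% and 83.1% of those called without it.

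**Figure D2:**
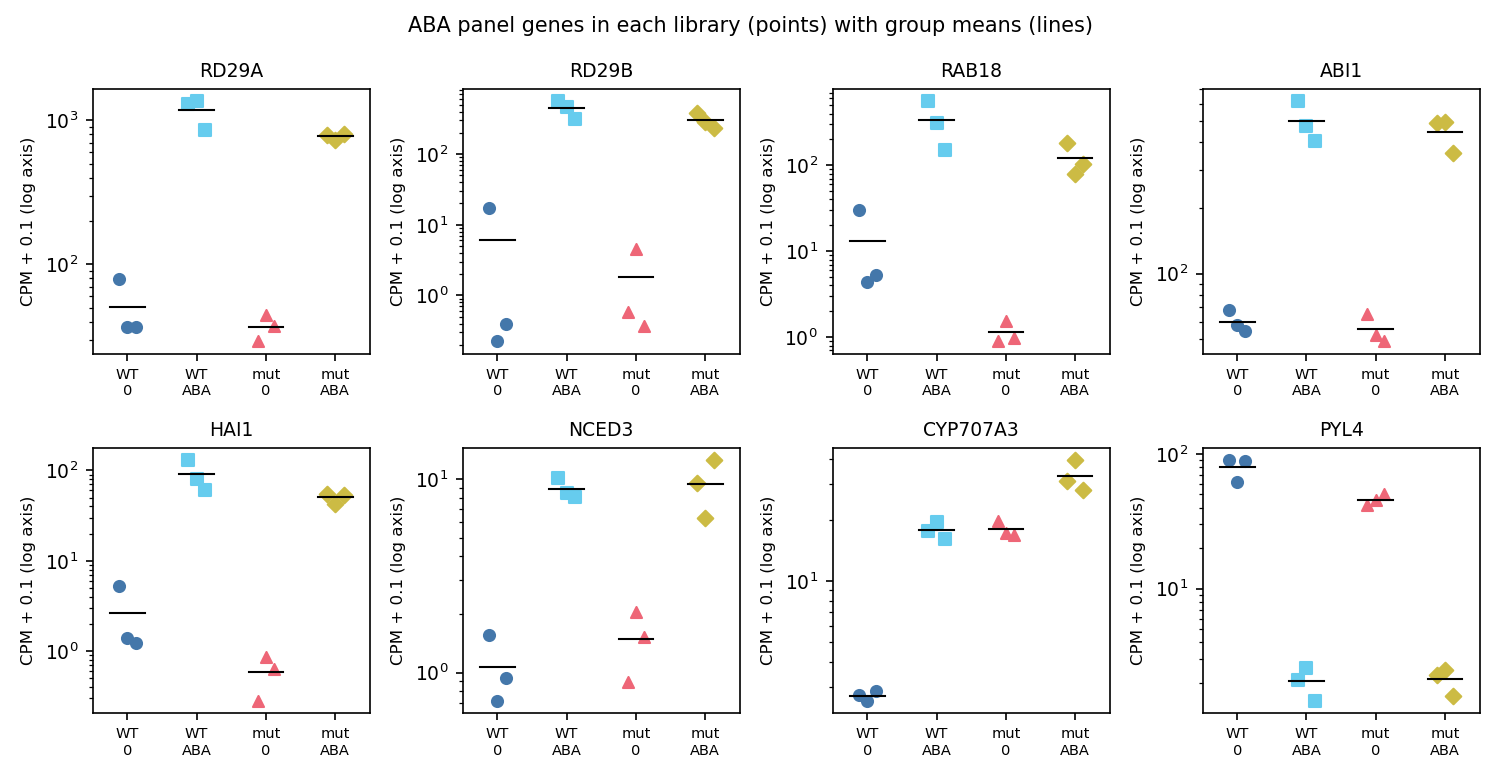
Level of the 8 panel genes in each library, as CPM plus 0.1 on a log axis, with wild type (WT) and mutant (mut) libraries untreated (0) or with ABA. Points are libraries and lines are means of 3. CYP707A3 stood at 2.62 CPM in untreated wild type and 17.9 CPM in the untreated mutant. RAB18 stood at 29.9 CPM in 1 untreated wild type library and at 4.25 and 5.17 CPM in the others.

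In the mutant, ABA raised as many of the ABA-induced markers as in wild type. RD29A rose by 4.40 ± 0.33 on the log2 scale, RD29B by 7.42 ± 1.34 (9.66 without mutant untreated replicate 2) and RAB18 by 6.86 ± 0.86. The wild type folds of RD29B and RAB18 depended on 1 untreated library, as given above. Of the 33 ABA-induced markers 31 rose, and so did all 8 clade A PP2C phosphatases, with the same numbers adjusted over the list alone (camera adjusted p = 5.15e-21 and 6.3e-08, and adjusted p = 0.0705 and 0.0912 with an estimated correlation). Of the 10 PYR/PYL ABA receptors 7 fell, with PYL4 at -4.48 ± 0.24, while PYL3, PYL7 and PYL9, chosen after their values were seen, rose by 2.26 ± 0.73, 1.21 ± 0.15 and 0.51 ± 0.16 (camera adjusted p = 0.0082, and adjusted p = 0.233 with an estimated correlation). Of the 10 SnRK2 kinases 6 rose and SNRK2.5, chosen after its value was seen, fell (-0.64 ± 0.20), and 7 of 9 ABA transcription factors and 10 of 11 genes of ABA synthesis and breakdown rose (camera adjusted p = 0.0082, 0.000101 and 1.99e-05, and adjusted p = 0.233, 0.0966 and 0.0705 with an estimated correlation). SWEET15 rose by 8.64 ± 0.70, and FTSH6, a protease gene with 0 counts in the untreated mutant, was at least 174-fold higher. CRK30, a receptor-like kinase gene, fell by 8.61 ± 0.35 (-9.27 without mutant ABA replicate 2), and AT3G27950, with 0 counts under ABA, was at least 110-fold lower. CYP707A3, whose enzyme inactivates ABA, rose by 0.88 ± 0.15.

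Of the 24 light harvesting and Rubisco small subunit genes, 2 rose and 5 fell in the mutant, and the list did not pass (median -0.34; camera adjusted p = 0.09). LHCB1.5 rose by 1.33 ± 0.28 and LHCB1.4, chosen after its value was seen, by 3.07 ± 0.91. RBCS1B and RBCS2B, for the small subunit of Rubisco, changed by -2.06 ± 0.36 and -1.65 ± 0.30. Without mutant untreated replicate 1, 10 of the 24 fell. Of 17 expansins, 10 fell and EXPA16 rose from 2.3 to 27.9 CPM, and 8 of 15 mitotic cell cycle genes fell (camera adjusted p = 0.000425 and 0.0105, and adjusted p = 0.382 and 0.531 with an estimated correlation). Counts of genes that rose were 11 of 16 for heat shock, 10 of 12 for flavonoid and anthocyanin synthesis, and 10 of 11 for leaf senescence (camera adjusted p = 1.75e-05, 2.64e-06 and 4.55e-05, and adjusted p = 0.0705, 0.162 and 0.276 with an estimated correlation). Of 19 salicylate and defence genes, 8 fell, among them WRKY18 at -1.63 ± 0.14 and CBP60G at -2.33 ± 0.29, and SARD1 and NIMIN1 rose by 0.85 ± 0.21 and 1.26 ± 0.36 (camera adjusted p = 0.0724, and adjusted p = 0.00215 by fry, lower). These 2 were chosen after their values were seen. Fry passed for all 11 lists that camera passed in the mutant and also for the clock, higher (adjusted p = 0.0483). In all, 4580 genes were higher and 4490 lower, 42.5% of those tested. The responses of both genotypes, which share no libraries but 1 model with a common spread per gene, overlapped in 3813 genes that rose and 3654 that fell. Independence would give 1154.8 and 1266, but the common spread can also raise such overlaps. Across genes, which are not independent replicates, log2 fold changes of the genotypes had a Pearson r of 0.884 and a Spearman rho of 0.841.

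**Figure D3:**
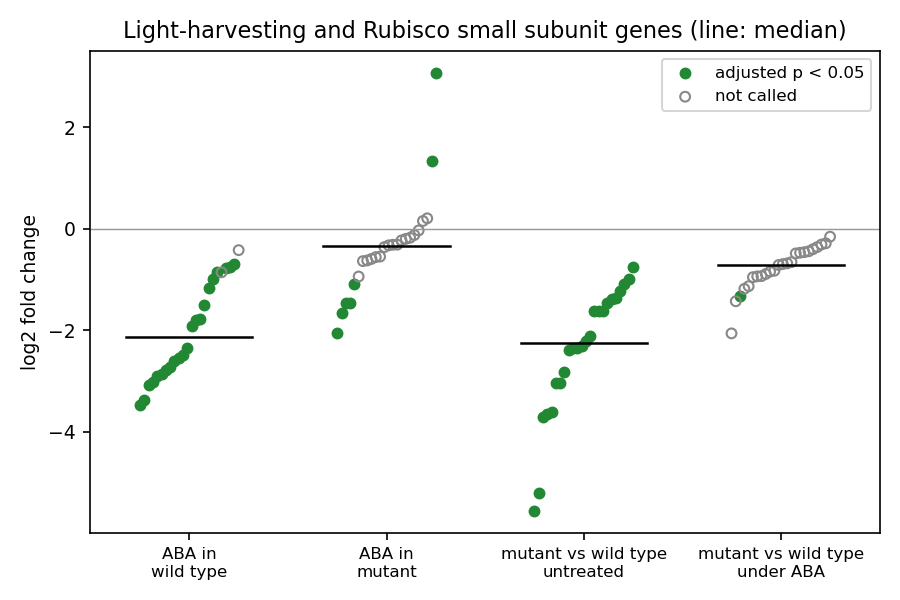
Log2 fold changes of the 24 measured light harvesting and Rubisco small subunit genes in 4 comparisons. Each circle is a gene, filled when its adjusted p was under 0.05, and the line is the median, at -2.13, -0.34, -2.25 and -0.70 from left to right.

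Untreated mutant seedlings held less mRNA of the photosynthetic antenna than untreated wild type. All 24 light harvesting and Rubisco small subunit genes were lower, also when adjusted over the list alone, with a median log2 fold change of -2.25 (camera adjusted p = 1.76e-17, and adjusted p = 0.476 with an estimated correlation). LHCB1.3, an abundant antenna gene, stood at 391.9 ± 198 CPM against 4890 ± 1290 CPM in wild type (-3.64 ± 0.40), LHCB1.5 at 5.44 ± 1.14 against 201.4 ± 16.8 CPM, and LHCB6 at 28.2 ± 6.01 against 342 CPM. After the length and GC correction 21 of the 24 were called and the median was -1.69, with LHCB1.3 at -2.44, LHCB1.5 at -3.02 and LHCB6 at -1.99. How reads shared between close LHCB1 or RBCS copies were assigned is not given in the sources used here, so values of single copies are less certain than that of the group. Expansins were lower in 8 of 17 cases (9 adjusted over the list alone), such as EXPA8 at -2.87 ± 0.28 and EXPA10 at -1.52 ± 0.15 (camera adjusted p = 1e-05, and adjusted p = 0.516 with an estimated correlation).

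Some defence genes were higher in the untreated mutant. Of 19 measured salicylate and defence genes, 9 were higher and PR5 was lower at -2.31 ± 0.36 (-1.17 after the length and GC correction), with 10 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.000479, and adjusted p = 0.296 with an estimated correlation). SARD1, a regulator of salicylate synthesis, was higher by 1.99 ± 0.23, the transcription factor gene WRKY18 by 1.85 ± 0.14, and ALD1 by 2.33 ± 0.36. MRD1 had the largest difference, at 34.8 ± 3.84 CPM against 0.119 ± 0.0575 CPM (log2 fold change 8.11 ± 0.28, adjusted p = 9.76e-09, higher in 3 of 3 libraries). Its untreated wild type libraries stood at 0.175, 0.123 and 0.0601 CPM, near the floor of 3 counts. The size of this fold is therefore less certain than its SE gives. Other large rises were ORA47, a transcription factor of the jasmonate response, at 5.10 ± 0.59 (5.71 without wild type untreated replicate 3), the disease resistance gene AT1G66090 at 3.84 ± 0.44 (4.66 without the same library), PP2-A5 at 3.43 ± 0.31, and QQS, a gene known for its effect on starch, at 3.31 ± 0.53 (4.01 without wild type untreated replicate 2). Of 7 CBF, DREB2 and ZAT factors, CBF1 and CBF2 were called higher. CBF1 went from 1 count in wild type, in replicate 1, to 69, a ratio of 57.6 with a counting interval of 10 to 2310, and CBF2 from 9 counts to 48. In this list 6 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0172, and adjusted p = 0.516 with an estimated correlation). Of 20 jasmonate synthesis and response genes 4 were higher, such as JAZ1 at 1.21 ± 0.27, and of 15 auxin early response genes 4 were higher and 3 lower (camera adjusted p = 0.0672 and 0.691).

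Of the ABA genes, CYP707A3 was 2.77 ± 0.17 higher on the log2 scale in the untreated mutant, and MYB96, a transcription factor of ABA signalling, 2.07 ± 0.23. Lower were 9 of the 33 ABA-induced markers (10 adjusted over the list alone), such as KIN1 at -3.47 ± 0.38 and COR15A at -1.99 ± 0.32, with a median of -0.75 (camera adjusted p = 0.0172, and adjusted p = 0.738 with an estimated correlation). Without wild type untreated replicate 1, in which RAB18 stood at 29.9 CPM against 4.25 and 5.17 CPM in the other 2 libraries, 7 of the ABA-induced markers were lower and their median was 0.000. RAB18 was lower by 3.64 ± 0.80 (-2.16 without wild type untreated replicate 1) and HAI1 was called lower, and both calls were lost after the length and GC correction, that of HAI1 also without wild type untreated replicate 1 or mutant untreated replicate 1. Of 10 PYR/PYL ABA receptors 5 were lower, with PYL6 at -1.33 ± 0.24 and PYR1 at -0.96 ± 0.17 (camera adjusted p = 0.0712). Of the other ABA lists, HAI1 was the 1 call among 8 clade A PP2C phosphatases, SNRK2.9 (0.67 ± 0.17) the 1 among 10 SnRK2 kinases, and MYB96, EEL and ANAC055 the 3 among 9 ABA transcription factors, with camera adjusted p = 0.583, 0.0712 and 0.445. Of 16 alternatives run for each, 4 lost the call of SNRK2.9, 5 that of EEL and 9 that of ANAC055, single left-out libraries among them. Lower genes numbered 4 of 14 for the circadian clock, 2 of 17 for root tissue markers, 4 of 19 for glucosinolate synthesis, 3 of 12 for flavonoid and anthocyanin synthesis, 2 of 15 for the mitotic cell cycle and 3 of 16 for heat shock, where HSFA7A was higher, a call that 4 of 16 alternatives lost (lowest camera adjusted p = 0.0592). By fry the light harvesting, expansin, defence and CBF, DREB2 and ZAT lists passed as by camera, the ABA-induced markers did not (adjusted p = 0.103), and the PYR/PYL ABA receptors, lower, and SnRK2 kinases and ABA synthesis and breakdown, higher, passed (adjusted p = 0.0154, 0.031 and 0.00316). No member of the 11 for leaf senescence was called by edgeR or limma-voom, 1 was called higher by DESeq2, and 1 was higher and 1 lower at an unadjusted threshold of 0.05 in edgeR.

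In all, 1869 genes were higher and 3153 lower in the untreated mutant. Properties of the libraries moved with these groups. Reads of rRNA, snoRNA and snRNA genes took 0.136 ± 0.0177% of counts in untreated wild type and 0.0864 ± 0.0097% in the untreated mutant, and organelle genes 0.108 ± 0.0224% and 0.0666 ± 0.0133%. Fold changes between untreated genotypes fell with GC content (Spearman rho -0.422 across genes, which are not independent replicates), from a median of 0.31 (log2) in the 10% of genes with the lowest GC to -0.64 in the 10% with the highest, and rose with exonic length (rho 0.282). After the correction 1743 genes were higher and 2117 lower, including 60.4% and 55.9% of those called without it. The rRNA genes AT2G01020 and AT3G41979 changed by -4.20 ± 0.36 and -4.01 ± 0.35 without the correction and by -1.85 and -1.65 with it. Leaving out mutant untreated replicate 1 gave 893 higher and 1927 lower genes, leaving out wild type untreated replicate 1 gave 1046 higher, wild type untreated replicate 2 gave 1974 lower and mutant untreated replicate 2 gave 1914 lower. Without the 2 first replicates together, 578 were higher and 1351 lower.

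**Figure D4:**
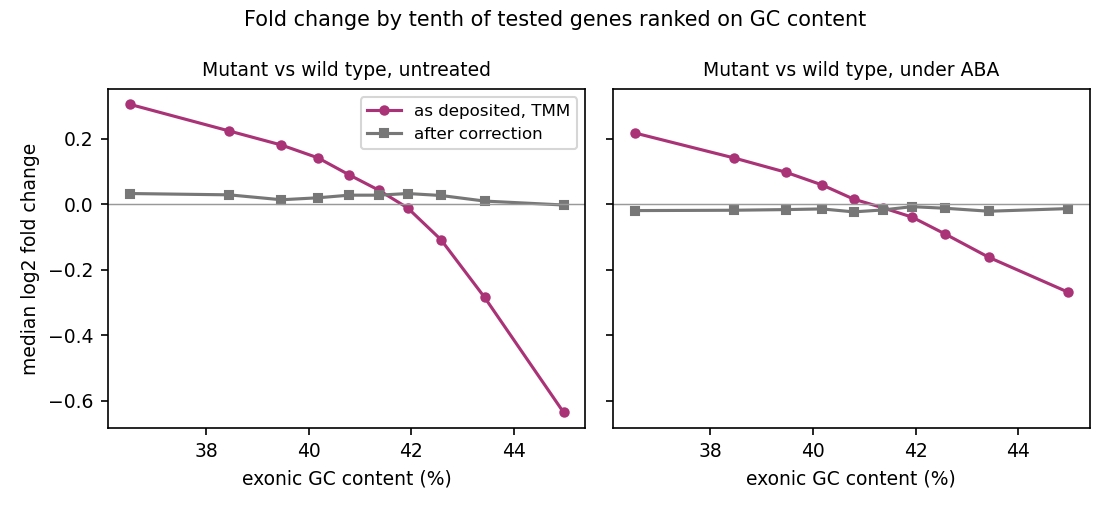
Median log2 fold change of mutant over wild type (vertical axis) in 10 bins of the tested genes ranked on exonic GC content in percent (horizontal axis), untreated on the left and under ABA on the right. The line with circles shows the TMM-scaled values, which fall from 0.31 to -0.64 untreated and from 0.22 to -0.27 under ABA, and the line with squares those after the length and GC correction.

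Under ABA the genotypes differed in fewer called genes, 344 higher and 38 lower in the mutant. MRD1 was again the most changed, with 2 counts in wild type and 1573 in the mutant, a ratio of 868 with a counting interval of 240 to 7170. AT2G24600, an ankyrin repeat gene, was higher by 3.84 ± 0.29, QQS by 3.59 ± 0.53 (4.38 without wild type ABA replicate 2), and the transcription factor genes WRKY53 and BHLH101 by 2.87 ± 0.24 and 2.73 ± 0.37. Lower were AT3G24750 at -1.47 ± 0.17, CDF3, a regulator of flowering time, at -1.33 ± 0.18, and the expansin gene EXPA10 at -1.13 ± 0.15. HEI10, the gene next to MRD1, was chosen after its values were seen and was higher in both genotype comparisons, by 1.12 ± 0.17 untreated and 1.94 ± 0.17 under ABA.

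**Figure D5:**
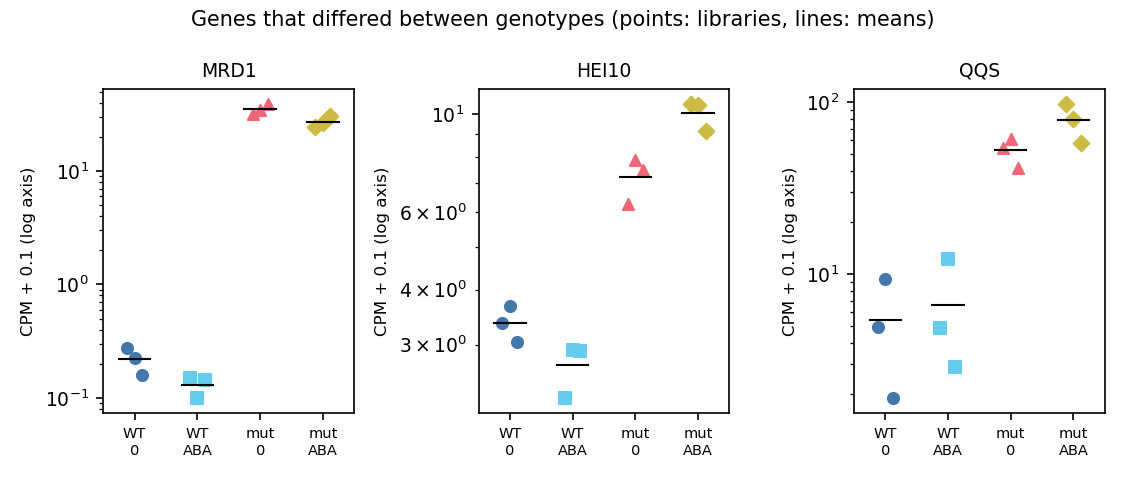
Level of MRD1, its neighbour HEI10, and QQS in each library, as CPM plus 0.1 on a log axis, with wild type (WT) and mutant (mut) libraries untreated (0) or with ABA. Points are libraries and lines are means of 3. MRD1 was at most 0.175 CPM in the 6 wild type libraries and at least 24.1 CPM in the 6 mutant libraries.

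Of the salicylate and defence genes, SARD1 (1.72 ± 0.22), WRKY70 (1.42 ± 0.29) and WRKY18 (0.95 ± 0.14) were higher under ABA, with 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.143). CYP707A3 was higher by 0.89 ± 0.15. The ABA-induced markers gave no call in edgeR or limma-voom and 1 lower call in DESeq2, and 4 were lower and 0 higher at an unadjusted threshold of 0.05 in edgeR, with RD29A at -0.60 ± 0.29 (adjusted p = 0.405) and RAB18 at -1.48 ± 0.63 (adjusted p = 0.34). Camera nonetheless placed the 33 ABA-induced markers lower as a set, with a median of -0.33 (adjusted p = 0.00147, and adjusted p = 0.779 with an estimated correlation). It placed lower also the 8 clade A PP2C phosphatases (median -0.51, with ABI1 at -0.16 ± 0.20), 19 glucosinolate synthesis genes (-0.23) and 14 circadian clock genes (-0.31), with adjusted p = 0.0293, 0.0116 and 0.0287, and adjusted p = 0.779 for each with an estimated correlation. In these 3 lists edgeR called no gene, DESeq2 called 1 lower in each and limma-voom 1 lower for glucosinolate synthesis, and 3, 2 and 4 were lower and 0 higher at an unadjusted threshold of 0.05 in edgeR, with 3, 1 and 1 lower adjusted over the list alone. Of the 24 light harvesting and Rubisco small subunit genes only LHCB1.5 was called (-1.33 ± 0.27, a call lost in 6 of 16 alternatives, the length and GC correction among them), 8 were lower adjusted over the list alone, and the median was -0.70 (camera adjusted p = 1.94e-10, and adjusted p = 0.779 with an estimated correlation). By fry none of these 5 lists passed for a shift in 1 direction, nor any other under ABA (lowest adjusted p = 0.293). Fry's test for changes in either direction passed for salicylate and defence (adjusted p = 9.91e-06). It also passed for the PYR/PYL ABA receptors, ABA synthesis and breakdown, and expansins (adjusted p = 0.00353, 0.00353 and 0.00452). The auxin, CBF, DREB2 and ZAT, and clock lists passed it too (adjusted p = 0.0199, 0.0228 and 0.0469). Single calls in other lists were IAA4 (1.06 ± 0.22) for auxin and AOC3 (0.77 ± 0.18) for jasmonate, lost in 5 and 10 of the 16 alternatives. The calls of WRKY70 and WRKY18 were lost in 5 and 1. Genes called in both genotype comparisons, which share no libraries but 1 model with a common spread per gene, numbered 287 higher and 25 lower. Independence would give 30.2 and 5.6, but the common spread and a GC trend in both comparisons can also raise the overlap. The GC trend was present under ABA too (rho -0.407 across genes), and 86.3% of the higher and 89.5% of the lower calls remained after the correction. DESeq2 called 591 higher and 164 lower, of which 78.3% were higher, a share lower than in edgeR by more than 10 percentage points. Counts of higher genes were 148, 181 and 215 without wild type ABA replicate 2, mutant ABA replicate 1 and mutant ABA replicate 2, and those of lower genes were 21, 19, 11, 11 and 24 without wild type ABA replicate 1 and 2 and mutant ABA replicate 1, 2 and 3.

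The ABA response of some genes differed between genotypes by the test of the interaction, with 354 genes more positive and 30 more negative in the mutant. The first set included light harvesting genes. LHCB1.5 changed by -2.55 ± 0.27 with ABA in wild type and by 1.33 ± 0.28 in the mutant, an interaction of 3.88 ± 0.39 (adjusted p = 0.00105), and LHCB6 by -3.47 ± 0.30 and -0.31 ± 0.28, an interaction of 3.16 ± 0.40. After the length and GC correction LHCB1.5 changed by -0.49 in wild type and 1.86 in the mutant, and the interactions of LHCB1.5 and LHCB6 were 2.35 and 1.98. In all, 6 of the 24 light harvesting and Rubisco small subunit genes were called and 18 adjusted over the list alone, with a median of 1.39 (camera adjusted p = 1.17e-15, and adjusted p = 0.291 with an estimated correlation). For LHCB6, the untreated mutant level of 28.2 ± 6.01 CPM lay near the 30.8 ± 3.41 CPM of wild type with ABA, both without the correction. PSBTN, for a small photosystem II protein, had an interaction of 3.06 ± 0.34, or 2.41 after the correction. KIN1 and KIN2, cold- and ABA-induced neighbours whose shared reads leave the split between them uncertain, rose more in the mutant (3.02 ± 0.49 and 2.09 ± 0.36). Each lost its call in 1 of 21 alternatives. Both started lower in the untreated mutant (-3.47 ± 0.38 and -2.38 ± 0.27), and neither was called between genotypes under ABA.

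More negative in the mutant were CYP707A3 at -1.88 ± 0.22 (adjusted p = 0.00172), MYB96 at -1.94 ± 0.31, NUDT21 at -2.35 ± 0.28 and ALD1 at -3.05 ± 0.50, all of which were higher in the untreated mutant. CYP707A3 went from 2.62 to 17.7 CPM with ABA in wild type and from 17.9 to 32.8 CPM in the mutant. Of 19 salicylate and defence genes, ALD1, PBS3 and WRKY18 were called, of which WRKY18 lost its call in 13 of 21 alternatives, PBS3 in 3 and ALD1 in 1 (6 adjusted over the list alone; camera adjusted p = 0.00669, and adjusted p = 0.267 with an estimated correlation). None of the other 7 panel genes passed, with RD29A at -0.14 ± 0.41 and RD29B at 1.19 ± 1.53. Of the PYR/PYL ABA receptors PYR1 was called at 1.15 ± 0.25, a call lost in 13 of 21 alternatives, and 4 adjusted over the list alone (camera adjusted p = 0.00102, and adjusted p = 0.267 with an estimated correlation). Of the expansins EXPA3 was called at 1.92 ± 0.29, and 8 adjusted over the list alone (camera adjusted p = 2.7e-06, and adjusted p = 0.351 with an estimated correlation). Camera also placed ABA synthesis and breakdown, where CYP707A3 was the 1 call, and the CBF, DREB2 and ZAT factors more negative and flavonoid and anthocyanin synthesis more positive (adjusted p = 0.00152, 0.0112 and 0.0353, and adjusted p = 0.267, 0.351 and 0.569 with an estimated correlation). For the latter 2 lists neither edgeR, DESeq2 nor limma-voom called a gene, and 1 was more negative and 3 more positive, respectively, at an unadjusted threshold of 0.05 in edgeR. By fry the PYR/PYL ABA receptors, ABA synthesis and breakdown and the light harvesting list passed (adjusted p = 0.0407, 0.0245 and 0.046), and the other 4 that camera passed did not (lowest adjusted p = 0.0777).

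Across the 6429 genes raised by ABA in the mean of both genotypes, the median interaction was -0.13 (log2), with 65.7% of responses smaller in the mutant (adjusted p = 0.366 over both sets, limma's fry). Across the 6877 lowered it was 0.18, with 65% smaller (adjusted p = 0.21, limma's fry), so neither set passed. The number of interaction calls depended on single libraries and on the tool. More positive genes numbered 202 and 181 without wild type untreated replicate 1 and 2, 150 without wild type ABA replicate 2, 218 and 117 without mutant untreated replicate 1 and 2, and 199 without mutant ABA replicate 3, and more negative genes fell to between 12 and 19 without any of these or wild type ABA replicate 1 or mutant ABA replicate 1. Without the first replicates of both untreated groups together 113 and 8 were called, and DESeq2 gave 693 and 89. Across genes, interactions correlated with exonic length (Spearman rho -0.372) and with GC content (rho 0.224). After the length and GC correction 237 and 37 were called, including 59.6% and 66.7% of those called without it, and the median interactions were -0.11 over raised genes and 0.06 over lowered genes, the latter down from 0.18.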

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

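The results in this part drew attention because the ABA response differed between the genotypes by the interaction test, and of the tests below, those of the root tissue markers and of the length and GC correction were chosen only after the data had been seen. Groups of 3 libraries were not tested for single libraries far from the others. The interaction was positive in 354 genes and negative in 30, where positive means a higher response in the mutant.

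Among genes of photosynthesis, the interaction was 3.88 (log2) for LHCB1.5, 3.16 for LHCB6, 2.82 for LHCB1.2, 2.55 for LHCB4.1, 3.06 for PSBTN and 3.08 for AT3G63540, a thylakoid lumen protein gene. After the length and GC correction the values were 2.35 for LHCB1.5, 1.98 for LHCB6, 1.91 for LHCB1.2, 1.69 for LHCB4.1 and 2.41 for PSBTN. For the rRNA genes AT2G01020 and AT3G41979 it was 3.91 and 3.80 (4.52 and 4.39 without wild type ABA replicate 1), and the correction lowered both by over 1.5 times, the latter to 1.99. AT2G43540 and AT1G19960 both had 3.34, while AT5G11550 had 3.21 and AT3G63390 had 3.08, values that were both 2 after the correction. Among stress, growth and receptor genes it was 3.02 for KIN1, 2.09 for KIN2, 1.92 for EXPA3 and 1.15 for PYR1.

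Negative interactions were -3.05 for ALD1, -1.86 for PBS3, -0.90 for WRKY18 and -2.00 for WRKY40 (-2.65 without wild type untreated replicate 3), all genes of defence, and -1.94 for MYB96 and -1.88 for CYP707A3, both of ABA signalling and turnover. The others were AT4G12735 at -3.04, AT5G45630 at -2.71, NUDT21 at -2.35, WAKL2 at -1.84, AT3G24750 at -1.69 and AR781 at -1.66. After the length and GC correction AT3G63390, AT4G12735, PBS3, AR781, PYR1 and WRKY18 were no longer called. Of 21 alternatives, AT4G12735 lost its call in 14, PYR1 and WRKY18 in 13, WRKY40 and AR781 in 12, WAKL2 in 10, PBS3 in 3, LHCB1.2 in 2, and AT3G63390, AT5G45630, KIN1, KIN2 and ALD1 in 1 each.

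The photosynthetic part of this pattern began in the untreated seedlings, where all 24 light harvesting and Rubisco small subunit genes were lower in the mutant, with a median log2 fold change of -2.254. The length and GC trend may account for part of it. As the whole cause, the trend that the correction removes was argued against by the corrected median of -1.691, with 21 still called. The correction cannot decide on other differences in library preparation. The rRNA genes AT2G01020 and AT3G41979, as given above, also stayed lower after it, by amounts near that median. Mutant untreated replicate 1 alone was argued against by a median of -2.018 with 22 called without that library. A smaller share of green tissue relative to root would raise the 17 root tissue markers, whose median was -0.321 and upper quartile -0.106 without the correction. These markers also changed with treatment, as 9 of the 17 were lower with ABA in wild type (median -1.02). They argue against a smaller green share only as far as they follow the amount of root. What stays open, as untested, is the genotype itself and differences in light, time of harvest, handling or library preparation between the untreated groups. The labels state no light, harvest time or handling for these groups. Library names of untreated wild type carry a number after the genotype, equal to the hours of ABA treatment, which the other groups lack. Whether that number marks a different harvest or handling is not given. On time of harvest, 4 of 14 circadian clock genes were lower in the untreated mutant, ELF4 (-1.06), LUX (-0.71), FKF1 (-0.94) and GRP7 (-1.47), and after the length and GC correction LUX alone of these 4 was still called (-1.14). The list as a whole passed neither camera nor fry for a shift in 1 direction (adjusted p = 0.657 and 0.481). Fry's test for changes in either direction passed (adjusted p = 0.00121), as it did for most lists in this comparison. A difference in time of harvest is therefore not excluded.

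For the 4 comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. In each, 1 of the 10 splits, the labels' own, gave as many calls. The real counts were 11388 for ABA in wild type, 9070 for ABA in the mutant, 5022 for the untreated genotypes and 382 for the genotypes under ABA, and the highest of the other splits were 0, 0, 0 and 1. The other splits mix the compared groups, which widens the spread within them and leaves few calls in any case. For the interaction, 11 of 100 regroupings of the genotypes within treatments, the real one included, gave at least the 384 calls. The highest other had 4448 calls, several times the real count. All 10 others with as many calls kept the untreated genotypes whole and mixed those under ABA, so the untreated genotype difference entered their interaction. Such regroupings do not stand for chance, so this count cannot decide whether chance gave the calls. Among the 82 regroupings with no treatment whole the highest count was 1. These mix the genotypes in every group, which widens the spread within groups, so their low counts cannot decide on chance either. The median interaction over genes raised by ABA (-0.125, highest other 0.314 in size) was reached in 28 of the 100, and that over genes lowered (0.181, highest other 0.5) in 31, so chance was not excluded for either. Both highest values came from a regrouping with the untreated genotypes whole, and such regroupings are among the 28 and 31. A regrouping with no treatment whole also reached the real medians, at -0.277 and 0.42.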

How the results depend on the processing

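Of the alternatives below, the length and GC correction and the exclusion of 2 libraries together were chosen only after the data had been seen. No call of a named gene or of a list turned to the other direction under any alternative run, and other genes were not checked for this. For named genes 8032 of the comparisons with an alternative kept their side of the threshold, 266 lost a call and 87 gained one, and of the numbers of genes called per list and direction, many of them 0, 3156 stayed within 1.5 times, 132 fell further and 112 rose further. Of 100 camera tests of lists, 41 passed. With an estimated correlation none of them passed, and with fry 10 lost and 11 gained the call. All 12 leading results stayed within 1.5 times of their value, or kept their call, with relative log expression factors, limma-voom, both other filters, the exclusion of organelle genes and the replicate block, which gave interaction medians of -0.13 and 0.19. DESeq2 gave more calls for mutant under ABA (591 higher, 164 lower) and interaction (693 and 89). A fit of only the compared groups gave 25 lower for mutant under ABA, and the length and GC correction 73. The cause was not tested. A minimum log2 fold change of 1, which by construction removes small changes, left 2271 higher and 3260 lower for ABA in wild type, 1974 and 2111 for ABA in mutant, 599 and 1539 for mutant untreated, and 196 and 20 for mutant under ABA.

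Leaving out single libraries, which leaves fewer samples, gave 893 to 2225 higher and 1914 to 3443 lower genes for mutant untreated, 148 to 296 and 11 to 46 for mutant under ABA, and 117 to 440 and 12 to 45 for interaction. For mutant untreated, counts moved by over 1.5 times without wild type untreated replicate 1 (1046 higher) and 2 (1974 lower) and mutant untreated replicate 1 (893 and 1927) and 2 (1914 lower). For mutant under ABA they did so without wild type ABA replicate 1 (21 lower) and 2 (148 and 19) and mutant ABA replicate 1 (181 and 11), 2 (215 and 11) and 3 (24 lower). For interaction they did so without wild type untreated replicate 1 (202 and 14) and 2 (181 and 15), wild type ABA replicate 1 (16 lower) and 2 (150 and 15), mutant untreated replicate 1 (218 and 18) and 2 (117 and 12), and mutant ABA replicate 1 (19 lower) and 3 (199 and 17). Without wild type untreated replicate 1 and mutant untreated replicate 1 together, mutant untreated had 578 and 1351 and interaction 113 and 8. The interaction medians were -0.18 to -0.06 over raised genes and 0.08 to 0.26 over lowered genes, with no test passed, and -0.11 and 0.06 after the length and GC correction. At this depth, a simulated 2-fold rise was called in 28% of genes for the interaction, so interactions of that size were often not detectable.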

Other observations

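Of the tests in this part, that of mislabelled libraries was chosen after the result was seen, and the per-library form of the carry-over test after its first form had been run, and genes named here outside the rule were chosen after their values were seen. Some single genes were higher in the mutant in both treatments. The resistance gene WRR4 was higher by 2.26 ± 0.20 (log2 ± SE, n = 3 per group) untreated and 1.83 ± 0.20 under ABA, AT1G63860 by 2.78 and 2.58, and the receptor-like kinase gene CRK10 by 2.42 and 2.09. The zinc finger gene SZF1 was higher by 2.82 ± 0.16 and 1.92 ± 0.15. FRO6 and FRO7, ferric reductase genes, were higher by 0.79 ± 0.19 and 0.58 ± 0.17 untreated and by 1.34 ± 0.20 and 0.85 ± 0.17 under ABA. The retroelement SADHU3-2 was lower by 4.41 ± 0.74 untreated and was called lower under ABA.

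In both genotypes, ABA lowered IRT1, the main iron uptake transporter gene of the root, by 7.12 ± 0.62 (log2) in wild type (-6.47 without wild type untreated replicate 2) and 6.25 ± 0.60 in the mutant, and the test of the difference gave 0.87 ± 1.01. Of 169 tested genes annotated as lncRNA, 29 rose and 31 fell with ABA in wild type, 25 rose and 9 fell in the mutant, 5 were higher and 32 lower in the untreated mutant, and 4 were higher and none lower under ABA. lincRNA11195 was not among the annotated names. AT3G01345 stood at 72.1 CPM in wild type untreated replicate 2 and 45 CPM in wild type ABA replicate 2, and at most at 1.68 CPM in the other 10 libraries. In wild type replicates 1, 2 and 3, QQS stood at 4.84, 9.23 and 1.8 CPM untreated and 4.78, 12.1 and 2.8 CPM with ABA.

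Wild type untreated replicate 1 held more ABA-induced transcripts than its replicates, with RAB18 at 29.9 CPM against 4.25 and 5.17, SWEET15 at 5.01 against 0.431 and 0.541, and HAI1 at 5.19 against 1.29 and 1.14. Carry-over of RNA from an ABA-treated wild type library would give every such gene 1 common share of its ABA level. Over 13 genes the 90th percentile of that share was 3.72, 6.68 and 8.38 times the 10th when taken against wild type ABA replicate 1, 2 and 3 in turn. The bound set beforehand, a ratio above 3 and beyond counting error (up to 2.28 for replicate 1), left out how much these genes vary between libraries. With that variation ratios up to 3.92, 3.96 and 4.08 are expected, which the ratios for replicates 2 and 3 exceeded and that for replicate 1 did not. Resampling the 13 genes gave 2.49 to 10.6, 2.69 to 12.9 and 3.0 to 18.5, so the excess for replicates 2 and 3 was within its spread. Carry-over, above all from replicate 1, and a response of the seedlings themselves cannot be told apart. A stress of these seedlings before harvest may be another cause and was not tested.

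The genes that differed between genotypes in both treatments included neighbours. Of 312 such genes, 13 pairs were adjacent among tested genes, against a median of 4 and a 95th percentile of 7 in 10000 random orders, which is consistent with neighbouring genes changing together. The pairs included MRD1 and HEI10, FRO6 and FRO7, and several of related resistance genes such as AT1G63860 and AT1G63880. Shared regulation of gene families, reads shared between copies, and local effects on the chromosome remain open. So do differences between the seed lines other than the mutation. A library with the wrong genotype label was argued against by the 20 genes that separated the genotypes most in the other treatment. By their median, every mutant library lay above every wild type library of its treatment, by 1.99 (log2) untreated and 0.70 under ABA, against ranges within groups of up to 0.28 and 0.43. An exchange of all libraries of both genotypes would not show in this test and remains open.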
